A study of Mus musculus with 738 samples.

How the data were processed

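Gene expression was measured in single cells of 4 mouse stem cell types, ES, PrES, XEN and TS cells, by sequencing RNA from cells sorted into wells. The series holds 738 libraries. Each well has 2 libraries with the same well and number, and these were summed into 1 cell, which gave 92 cells of each type. The remaining 2 libraries hold reads assigned to no well and entered no comparison. The labels do not say what the 2 parts of a well are. For genes with at least 20 counts over both parts, the parts of a cell differed by a median of 1.09 to 1.10 times the Poisson variance in each type (at most 1.21), against at least 24.0 for parts of different cells, so they were counted as 1 sample.

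The deposited values are estimated counts per gene, listed as whole numbers. Reads were trimmed with Trim Galore 0.6.4 and quantified with kallisto 0.46.2, and the build is mm10, per the submitters' processing notes. The gene annotation and how the estimates became whole numbers are not given in the sources used here. Whether strand was used is not given either, so genes and their antisense partners such as Xist and Tsix, and families of near-identical copies such as Rhox4 and Zscan4, have uncertain levels. The table has 36040 genes, of which 34964 (97.0%) matched the RefSeq annotation of the same build by symbol (32515), gene number (1414) or synonym (1035). Coordinates come from that annotation and count from 1. The table has no mitochondrial genes under an mt- name.

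The counts of each cell were divided by its total to give counts per 1000000 (CPM). Cells with fewer than 2000 detected genes were to be left out, but none was that low. The labels describe 1 cell per well, and no doublet caller was run. Levels are means over cells with the SD over cells, and ratios are log2 of the means after adding 1 CPM, which understates the ratios of low genes. The labels name no culture, animal or line for a cell, so each type is 1 sample and no test was made. Shares of cells have exact Clopper-Pearson intervals and summed counts exact Poisson intervals at 95% confidence. Both cover counting error only, since the reads carry no molecular identifiers in the sources used here. A gene with no count in a type was set against a floor of 3 counts over all cells of the type.

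All choices named here were fixed before the data were examined unless stated. A total of 21 gene lists were fixed: epiblast and naive pluripotency, formative pluripotency, primitive endoderm core, parietal endoderm, visceral endoderm, trophoblast stem, differentiated trophoblast, fibroblast (feeder cells), 2-cell-like, WNT targets, FGF/ERK targets, FGF and PDGF ligands and receptors, DNA methylation, epithelial-mesenchymal, S phase, G2/M, stress and p53, glycolysis, sterol (cholesterol) synthesis, imprinted, and X inactivation with Y-linked genes. Some genes are in more than 1 list, for example Krt8 and Krt18. A member was measured when its mean was at least 1 CPM in either type, and a list with fewer than 3 measured members gave no ratio. The median log2 ratio of a list was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Outside the lists, the named genes are the 10 with the largest ratio each way among genes with a mean of at least 10 CPM in the higher type and a count in at least 50% of its cells, leaving out predicted, ribosomal and mitochondrial genes and names without a symbol (LOC names among them). The named variable genes are the 10 with the largest squared coefficient of variation relative to the 200 genes nearest in mean, among genes with a mean of at least 50 CPM.

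Similarity of mean profiles was computed over genes with a mean of at least 1 CPM in any type. Principal components of all cells used the 2000 genes with the largest variance of log2(CPM + 1). Within each type, cells were divided into 2 groups by k-means on 10 components of the 1000 genes with the largest excess variation, and the silhouette was set against 20 shuffles of each gene across cells. Genes per cell were also counted after thinning to 500000 counts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

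The steps were tested on simulated counts. Of 200 genes changed 4-fold, 199 were found at 2-fold or more in the simulated comparison of PrES with XEN cells, 198 in that with ES cells and 199 in that with TS cells, with 36040 genes simulated in each. Of the unchanged genes with at least 10 CPM, 0.562%, 0.626% and 0.587% passed the same limit. Both sides were drawn from the means and spread of PrES cells, with genes varying independently, and only the totals came from each type. The simulation held no differences between cultures, no reads from other wells and no added outlier cells. These shares are therefore not error rates of the real comparisons. A simulated group of 30 among 91 PrES cells with 200 genes raised 8-fold gave a silhouette of 0.302 against 0.0668 without it, and all cells were put on the right side.

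The alternatives were other pseudocounts (0.1 and 10), no filter on low values or a higher one, the median or the mean of logs over cells in place of the mean, centring of the ratios, each part of a cell alone, plate rows A to D or E to H alone, other cell filters, other detection limits, thinning, 100 nearest genes, the variance of logs, and leaving out the cell cycle lists. Chosen after the data were seen were leaving out cells under 500000 counts, leaving out 1 XEN cell with fibroblast genes, and CPM without LOC101056014, which held a mean of 3.18%, 2.99%, 3.98% and 2.34% of the counts of ES, PrES, XEN and TS cells and 28.8% in 1 ES cell. With no replicates, a value was taken as moved when a log2 ratio changed by more than 1.5-fold, a correlation or silhouette by over 0.05, a percentile by over 10 or a share beyond its interval, which are limits set for this purpose.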

Results

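Single-cell RNA sequencing was used to ask whether the cells within 4 kinds of mouse stem cell cultures were alike or mixed. The cultures were embryonic stem (ES) cells, which correspond to the epiblast of the blastocyst, primitive endoderm stem (PrES) cells, extraembryonic endoderm (XEN) cells, which are long-established endoderm lines from the blastocyst, and trophoblast stem (TS) cells. Each kind was represented by 92 cells. Every cell had been deposited as 2 libraries from the same well, which were summed. Total counts per cell ranged from 117511 to 3506878, with medians of 2078968 in ES, 2044978 in PrES, 2190649 in XEN and 2227500.5 in TS cells. Between 5787 and 11620 genes were detected per cell, and no cell fell below the minimum of 2000 genes. The median number of genes per cell was 8739.5 in ES, 8769.5 in PrES, 8726 in XEN and 9849.5 in TS cells. After thinning every cell to 500000 counts it was 7286, 7280.0, 7168 and 8130.0, with 1 ES, 1 PrES and 1 XEN cell left out as too shallow. These 3 cells held 147954, 117511 and 334567 counts.

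The labels do not say which line or culture a cell came from, so each cell type counted as 1 sample. No test between types was made, and no p-value is given. Levels are counts per 1000000 (CPM), given as the mean ± SD over the 92 cells of a type. The SD describes the spread of cells and is not an error of the type. Ratios are log2 ratios of the mean CPM plus 1, and a list member was counted as higher or lower only at 2-fold or more. Intervals for shares of cells are 95% Clopper-Pearson intervals and cover counting error only. ES cells were labelled with another strain (B6N129X1F1) than the other types (CD-1), so strain and type could not be told apart for ES cells. Each type also had its own plate.

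Marker genes of each lineage were compared first. ES cells had high levels of the pluripotency genes Nanog (1099 ± 449 CPM), Pou5f1 (279.5 ± 120.8) and Sox2 (34.8 ± 31.4). PrES and XEN cells had the primitive endoderm factors Gata6 (96.9 ± 93.1 and 97.96 ± 96.3), Sox17 (333.9 ± 255.7 and 1515 ± 911) and the growth factor receptor gene Pdgfra (185.01 ± 133.8 and 255.4 ± 164.3). In ES cells Gata6 was at 0.380 CPM. TS cells had the trophoblast factors Gata3 (849 ± 541), Hand1 (1094 ± 1063), Eomes (260.97 ± 177.99) and Cdx2 (23.4 ± 40.3), as well as Sox2 (48.3 ± 37.4). The median log2 level over list members was 7.80 for the primitive endoderm core list in PrES and 7.10 in XEN cells and 7.68 for the trophoblast stem list in TS cells. Afp, Apoa4 and Ttr, genes of mature visceral endoderm, were scarce: Afp and Apoa4 had no count in PrES cells, and Ttr was at 0.139 CPM there and 4.90 CPM in XEN cells.

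**Figure D1:**
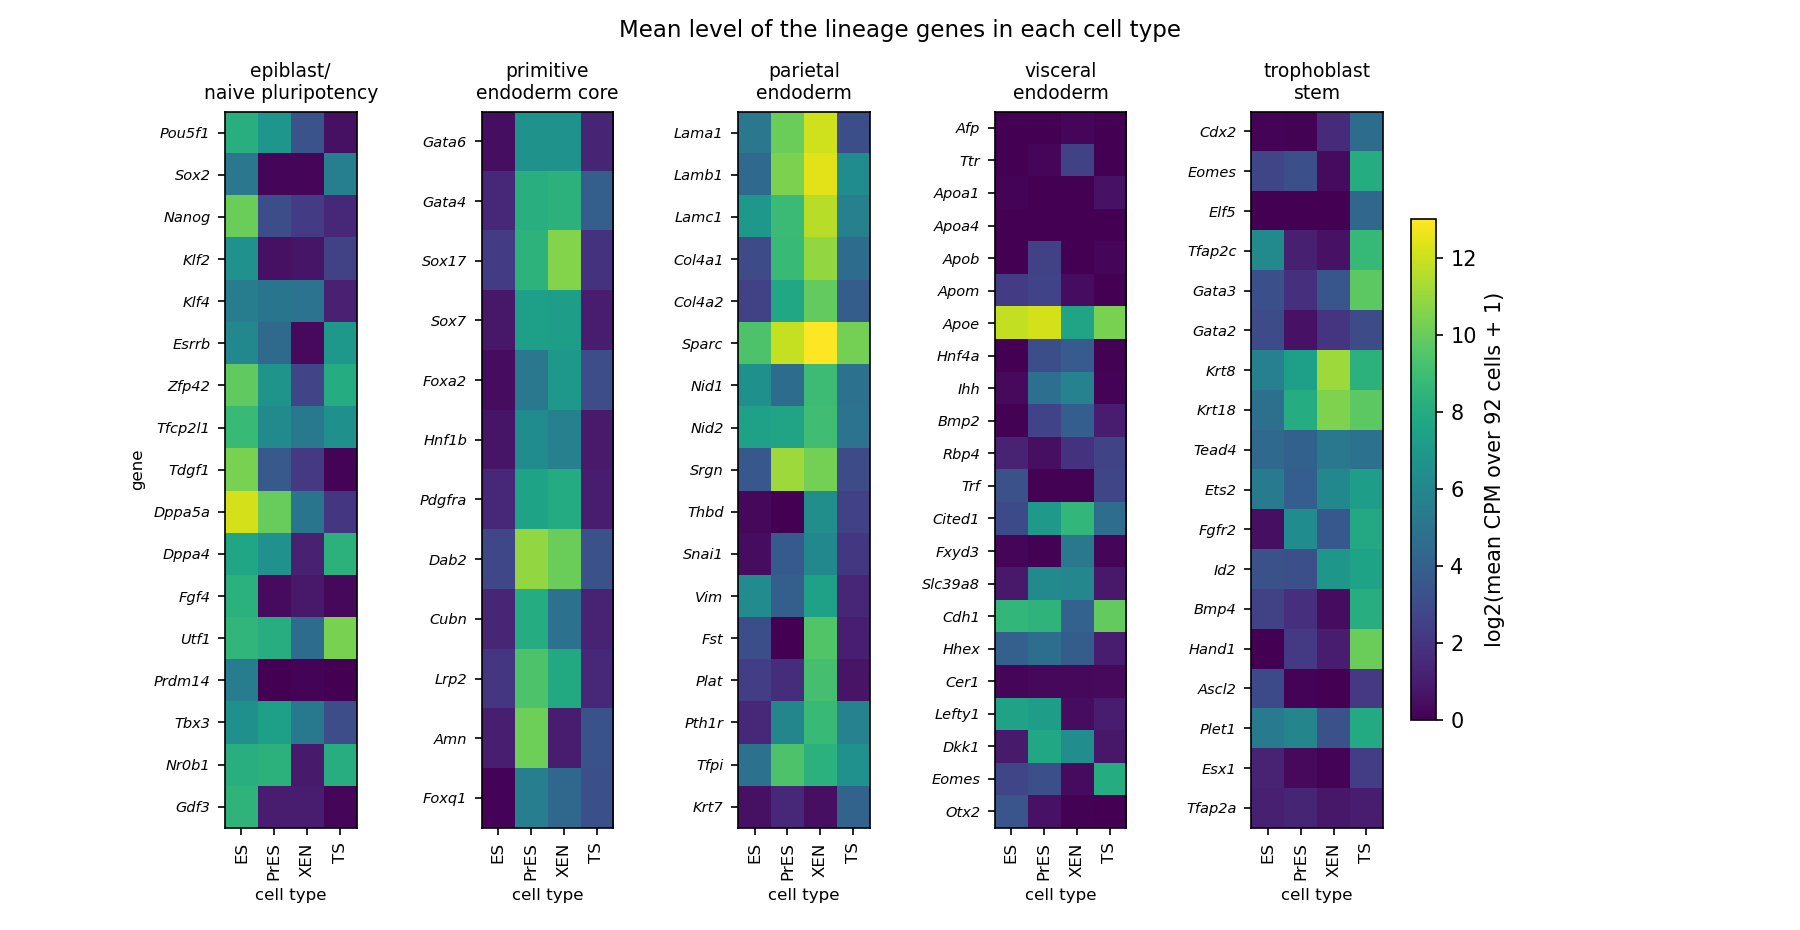
Mean level of the genes of 5 lineage lists in ES, PrES, XEN and TS cells, as log2 of the mean CPM over 92 cells plus 1 (color scale). PrES and XEN cells both have genes of the primitive endoderm core list, of which 6 of 12 are within 2-fold between them. Another 4 are higher in PrES cells (Amn, 1112 against 1.07 CPM) and 2 in XEN cells. Gata4 is among the 6, but without cells under 500000 counts its log2 ratio is -1.03, toward XEN cells. Pou5f1 is at 113.95 CPM in PrES cells, between the 279.5 CPM of ES and the 8.89 CPM of XEN cells.

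The mean profile of PrES cells was closest to that of XEN cells. Across 15472 genes the Pearson correlation of the log2 mean profiles was 0.90 for PrES and XEN, 0.848 for PrES and TS and 0.845 for PrES and ES. The other pairs lay between 0.816 (ES and XEN) and 0.834 (ES and TS). These correlations are across genes, which are not independent replicates. In a principal component analysis the first 3 components held 11.6%, 9.17% and 5.40% of the variance, and every cell lay nearest to the center of its own type on these 3 components. This measure places any cell with 1 of the 4 types, so it does not show what a cell is. The XEN cell of well B11, which had fibroblast genes, was also nearest to the XEN center. The order in which PrES and XEN were the most similar pair held under every gene filter and pseudocount tried.

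**Figure D2:**
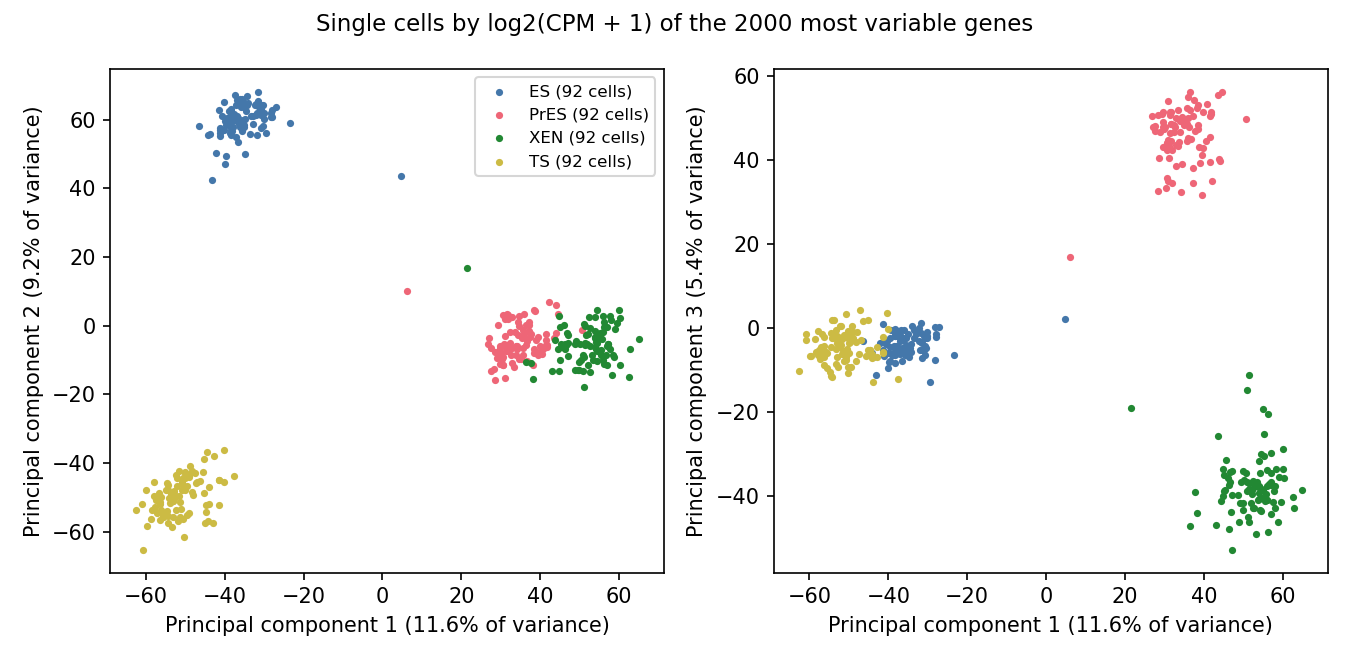
Each point is 1 cell (92 of each type), placed by principal components of log2(CPM + 1) over the 2000 genes of largest variance and colored by type; axis labels give the share of variance. All cells, the XEN cell with fibroblast genes among them, lie nearest to the center of their own type. The third component, with 5.40% of the variance, parts PrES from XEN cells.

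Against XEN cells, the medians of 6 fixed lists lay beyond those of every random list of like expression. The epiblast and sterol synthesis lists were higher in PrES cells, and the parietal endoderm and epithelial-mesenchymal lists were higher in XEN cells. So were the trophoblast stem list, whose sign turned under 3 settings (0.014 to 0.33), and the fibroblast list, the latter because of 1 XEN cell. Of 13 measured epiblast genes, 9 were at least 2-fold higher in PrES and none was at least 2-fold higher in XEN cells, with a median log2 ratio of 3.51, higher than in any of 10000 random lists of like expression. Of these 9, Tdgf1 (1.495) turned its sign with means of logs (-0.56) and medians over cells (-0.99). Pou5f1 was 113.95 ± 72.6 CPM against 8.89 ± 37.4, Nr0b1, a nuclear receptor of the pluripotency network, 323.2 ± 240.9 against 0.924 ± 0.789, Dppa5a 1019.8 ± 324.9 against 31.9 ± 99.7, and Zfp42 103.5 ± 81.3 against 5.52 ± 13.2. Nanog and Sox2 were not among them: Nanog was at 7.51 and 3.91 CPM and Sox2 at 0.129 and 0.128 CPM. Of the 17 parietal endoderm genes, 14 were at least 2-fold higher in XEN cells and 1 was at least 2-fold higher in PrES cells (Tfpi, 667 ± 321.9 against 312.1 ± 371.03), with a median of -2.08, lower than in any random list. They included the basement membrane genes Lama1 (1085 ± 516 against 4204 ± 2135), Lamc1 (458 ± 382.3 against 3107 ± 1497) and Col4a1 (448 ± 261.2 against 1869 ± 1051). Of 17 sterol synthesis genes, 14 were at least 2-fold higher in PrES cells (median 2.33, above every random list), among them Sqle, squalene epoxidase (709 ± 366.3 against 94.1 ± 142.6), and Lss, lanosterol synthase (341.1 ± 224.7 against 25.4 ± 47.6). Across the alternative settings the epiblast median lay between 1.495 (no filter on low values) and 3.56, and the parietal median between -2.24 and -2.04.

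The primitive endoderm core genes were split between these populations. Gata6 (-0.02), Sox7 (0.09), Pdgfra (-0.46), Hnf1b (0.69), Dab2 (0.78) and Gata4 (-0.13) were within 2-fold. Sox17 (-2.18) and Foxa2 (-1.70) were higher in XEN cells. The genes of the endocytic receptor complex of endoderm were higher in PrES cells: Amn at 1112 ± 612 against 1.07 ± 7.49 CPM, Cubn at 266.7 ± 223.8 against 28.9 ± 63.1 and Lrp2 at 657 ± 433 against 240.6 ± 188.9. Foxq1 was also higher in PrES cells (1.19). The Gata4 value of PrES cells, 294.6 ± 1313 CPM, rested on the shallow cell of well A1: without it the mean was 158.2 ± 109.8 CPM and the log2 ratio was -1.03.

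Among all genes, the 10 with the largest ratios toward PrES cells were Amn, Spp1 (osteopontin), Pfkp (a phosphofructokinase), Nr0b1, Alpl (alkaline phosphatase), Lefty2 and Lefty1 (inhibitors of Nodal), Bin2, Lcp1 (an actin-bundling protein) and Foxh1 (a partner of the Smads in Nodal signaling), with log2 ratios from 6.74 to 9.07. Spp1 was at 2595 ± 2017 CPM in PrES and 5.71 ± 2.96 in XEN cells. The 10 with the largest ratios toward XEN cells were Fst (follistatin), Epas1 (HIF-2α), Frzb (a secreted WNT antagonist), Ctgf, Lamc2 (a laminin chain), Plat (tissue plasminogen activator), Timp2, Cryab, Ptger3 (a prostaglandin receptor) and Wfdc1, with log2 ratios from -6.62 to -9.45. Fst was at 710.0 ± 601 CPM in XEN cells and had 3 counts in all 92 PrES cells together, a pooled level with an exact Poisson interval of 0.00334 to 0.0473 CPM. Wfdc1 was at 97.5 ± 158.4 CPM in XEN cells and had no count in PrES cells. Its pooled level over all XEN cells, 100.8 CPM, was at least 6231-fold higher than in PrES cells, against a floor of 3 counts over all PrES cells (0.0162 CPM). Amn lies on chromosome 12 at 111271096 to 111276426 and Fst on chromosome 13 at 114452262 to 114458989 (mm10, protein-coding genes).

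The other lists differed from XEN cells in both directions. DNA methylation genes had a median log2 ratio of 1.29, with 5 of 8 at least 2-fold higher in PrES cells (Dnmt3l, a cofactor of de novo methylation, 137.6 ± 116.7 against 5.61 ± 22.8 CPM). FGF/ERK targets had 1.15, with 5 of 10 at least 2-fold higher, among them Dusp4 (69.4 ± 69.1 against 6.21 ± 16.4) and Egr1 (3.57), and WNT targets had 1.39 with 5 of 6 at least 2-fold higher, all 5 at low levels (Tcf7, the highest of them, 15.6 ± 31.6 CPM in PrES cells). The epithelial-mesenchymal list had -2.34, with 7 of 12 at least 2-fold higher in XEN and 3 in PrES cells: Cdh1, E-cadherin, was higher in PrES cells (4.33), while Vim (-3.47), Krt8 (-3.77), Krt18 (-2.44) and Krt19 (-2.65) were higher in XEN cells. The visceral endoderm list had 0.51 (7 of 16 higher and 5 lower by at least 2-fold), with Apoe at 4541 ± 2085 against 190.1 ± 322.3 CPM and Cited1 at 129.1 ± 124.9 against 386 ± 453. The trophoblast stem list had -1.18 (5 of 15 higher and 8 lower by at least 2-fold), with the keratins Krt8 and Krt18 and Id2 (-3.70) in XEN cells and Fgfr2 (2.74) in PrES cells, and its sign turned with medians over cells (0.33), in plate rows E to H (0.014) and with no filter on low values (0.055), while means of logs gave -2.67e-04. Imprinted genes had -1.01, which was -0.27 without the XEN cell with fibroblast genes and turned to 0.082 with medians over cells and 0.16 with means of logs. The medians of the remaining lists were for stress and p53 genes -0.73, FGF and PDGF ligands and receptors -0.45, glycolysis 0.37, S phase -0.31, G2/M -0.37, X- and Y-linked genes 0.31 and differentiated trophoblast genes -1.40 (3 measured). The fibroblast list had -3.23, which came from 1 XEN cell and was -0.13 without it. With medians over cells the visceral endoderm, differentiated trophoblast, fibroblast, WNT and X- and Y-linked lists had 0, as had the differentiated trophoblast list with no filter on low values. Among the random lists, the percentile of the median was 99.98 for DNA methylation, 99.9 for FGF/ERK targets, 98.9 for WNT targets and 98.3 for glycolysis. It was 96.9 for the visceral endoderm list and also for the primitive endoderm core list, 72.4 for X- and Y-linked genes, 7.80 for FGF and PDGF ligands and receptors, 1.16 for S phase, 1.08 for differentiated trophoblast, 0.38 for G2/M, 0.26 for stress and p53 and 0.09 for imprinted genes, all with every cell kept. Only 2 formative pluripotency genes reached a mean of 1 CPM in PrES or XEN cells, and no gene of the 2-cell-like list did in any type, so these lists gave no ratio here. Against ES and TS cells only 2 differentiated trophoblast genes were measured, which gave no ratio either.

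PrES cells were set apart from ES cells by the whole primitive endoderm program and by lower levels of most pluripotency genes. All 12 primitive endoderm core genes were at least 2-fold higher in PrES cells, with a median log2 ratio of 6.35, higher than in any random list. Of the 17 epiblast genes, 13 were at least 2-fold higher in ES cells and none in PrES cells (median -2.51, lower than in any random list). Nanog was 1099 ± 449 CPM in ES against 7.51 ± 19.9 in PrES cells, Fgf4 316.9 ± 218.01 against 0.325 ± 0.403, Tdgf1, a Nodal co-receptor, 1335 ± 700.3 against 11.5 ± 73.2, and Klf2 94.4 ± 55.6 against 0.491 ± 2.48. The differences were smaller for Pou5f1 (-1.29), Dppa4 (-1.11) and Esrrb (-1.59), and 4 genes were within 2-fold: Nr0b1 (0.17), Utf1 (-0.46), Klf4 (-0.43) and Tbx3 (0.80). Parietal endoderm genes were at least 2-fold higher in PrES cells for 10 of 16 members (median 2.89, above every random list), among them Lamb1 (1392 ± 763 against 21.1 ± 21.6) and Lama1 (4.91), while Nid1 (-1.95), Vim (-2.29) and Fst (-3.08) were higher in ES cells.

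The 10 genes with the largest ratios toward PrES cells were Amn, Dab2 (an endocytic adaptor), Prnp (prion protein), Cep112it, Srgn (serglycin), Aqp8 (aquaporin 8), Habp2, Lrp2 (megalin), Ctsh (cathepsin H) and Rhox5 (a homeobox gene of the X chromosome), with log2 ratios from 7.24 to 9.05. Dab2 was at 1869.5 ± 1084 CPM against 5.92 ± 6.93 and Prnp at 11141 ± 4070.5 against 40.9 ± 32.4. Such low values may hold reads from other wells, as described under the other observations. For the 50 highest PrES genes under 5% of their level there, the median was 0.998% in ES and 0.776% in TS cells. Ratios against ES and TS cells may therefore be too small. The 10 toward ES cells were Trh (thyrotropin-releasing hormone), Fgf4, Igfbp2, Calcoco2 (an autophagy receptor), Gdf3, Fn1 (fibronectin), Ifitm1, Jam2, Slc7a3 (an amino acid transporter) and Fxyd6, with log2 ratios from -7.17 to -8.36. Trh was at 677 ± 799 CPM against 1.06 ± 2.76. S phase genes were at least 2-fold higher in ES cells for 10 of 18 members (median -1.14, lower than in any random list), for example Mcm2, a subunit of the replicative helicase (909 ± 373.8 against 266.6 ± 201.3), and G2/M genes for 5 of 18 (median -0.69).

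The other lists differed between PrES and ES cells in both directions. Visceral endoderm genes had a median of 0.60 (7 of 16 at least 2-fold higher in PrES and 2 in ES cells; 0 with medians over cells), with Cited1 (4.12), Ihh (4.42) and Dkk1 (6.81) higher in PrES cells. DNA methylation genes had -0.84: Dnmt3b (2.00), Dnmt3a (1.02) and Tet3 (2.78) were higher in PrES cells and Dnmt1 (-1.47), Uhrf1 (-1.61), Tet1 (-2.66) and Tet2 (-2.41) in ES cells. Sterol synthesis genes had 0.63 (5 of 17 at least 2-fold higher in PrES cells), WNT targets 0.65, FGF/ERK targets 0.52, FGF and PDGF ligands and receptors 0.48 with a mean of -0.09, epithelial-mesenchymal genes 0.38, stress and p53 genes 0.07, glycolysis 0.04 with a mean of -0.02, trophoblast stem genes -0.24, X- and Y-linked genes 0.44, formative pluripotency genes 1.07 (3 measured) and fibroblast genes 0.84 (3 measured; 0.06 without the cells under 500000 counts). Imprinted genes had -1.08, with 6 of 13 at least 2-fold higher in PrES (Grb10, 3.33; Igf2, 3.05) and 7 in ES cells (Meg3, -5.64; Plagl1, -5.03), and the sign of the median turned to 0.67 with medians over cells and 0.12 with means of logs. The trophoblast stem median turned to 0.56 and 0.31 under the same settings and to 0.28 in plate rows E to H. Signs also turned for glycolysis (4 settings, -0.27 to -0.026), stress and p53 (-0.08 in rows E to H and -0.037 without the cells under 500000 counts), FGF and PDGF ligands and receptors (-0.25 with a pseudocount of 0.1), WNT targets (-0.13 with no filter on low values) and fibroblast genes (-0.035 in rows E to H). With medians over cells the last 4 of these lists and the formative pluripotency and X- and Y-linked lists had 0, as had the fibroblast list with no filter on low values.

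Against TS cells, PrES cells again had higher endoderm genes and had lower trophoblast genes, while the pluripotency genes were divided between both types. All 12 primitive endoderm core genes were at least 2-fold higher in PrES cells (median log2 ratio 6.42, above every random list), and 16 of 18 trophoblast stem genes were at least 2-fold higher in TS cells (median -2.87, below every random list). Gata3 was 849 ± 541 CPM in TS against 2.51 ± 1.502 in PrES cells, Tfap2c 414 ± 204.4 against 1.18 ± 1.16, and Bmp4 271.5 ± 254.7 against 2.55 ± 9.97. Of 14 measured epiblast genes, 6 were at least 2-fold higher in PrES cells, including Pou5f1 (6.27) and Dppa5a (7.93), and 6 in TS cells, including Sox2 (-5.45), Esrrb (-2.45) and Utf1 (-2.27). The median of this list was -0.03 and its mean 0.87, so they differed in sign. Parietal endoderm genes were at least 2-fold higher in PrES cells for 12 of 17 members (median 2.56) and visceral endoderm genes for 11 of 15 (median 2.37), both above every random list. Of the 12 parietal genes, Plat (1.02) turned its sign with means of logs (-0.46), with medians over cells (-0.56) and in plate rows A to D (-0.23). With medians over cells the visceral endoderm value was 0, and with a pseudocount of 10 it was 0.82.

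The 10 genes with the largest ratios toward PrES cells were Srgn, Dppa5a, Lrp2, Npl, Spp1, Dab2, Aqp8, Klb (beta-klotho, an FGF co-receptor), Gja1 (connexin 43) and Habp2, with log2 ratios from 7.19 to 8.07. The 10 toward TS cells were Gata3, Hand1, Cldn3 (a tight junction protein), Slc38a4 (an amino acid transporter), Tfap2c, Prss50, Gdf6, Ccdc3, Sorl1 and Rhox4g, with log2 ratios from -7.06 to -7.92. Rhox4g belongs to a family of near-identical copies, so its level is uncertain. FGF/ERK targets were at least 2-fold higher in TS cells for 8 of 11 members (median -1.51), for example Dusp6 (509.8 ± 589 against 14.4 ± 30.1) and Spry4 (156.7 ± 121.4 against 34.9 ± 45.4). Imprinted genes were at least 2-fold higher in TS cells for 8 of 11 (median -2.84, below every random list), for example H19 (-6.85), Cdkn1c (-6.88) and Mest (-6.33). X- and Y-linked genes had 3.56, with the 4 Y-linked genes higher in PrES cells and Xist (-3.68) and Tsix (-1.01) in TS cells. The median of all genes was itself shifted by -0.11 in this comparison, more than in those with XEN (0.04) and ES cells (-0.03). Of the 5 lineage lists only the epiblast list, whose median lay between -0.21 and 0.30 over the alternative settings, turned its sign when this shift was set to 0. It also turned with means of logs, with medians over cells, in plate rows A to D and with no filter on low values. The remaining medians were -1.20 for formative pluripotency (6 measured; Pou3f1, -5.52), -1.24 for FGF and PDGF ligands and receptors with a mean of 0.02, -0.89 for stress and p53, -0.68 for G2/M, -0.57 for S phase, -0.35 for DNA methylation with a mean of 0.59, 0.30 for sterol synthesis, 0.14 for epithelial-mesenchymal, 0.06 for WNT targets with a mean of -0.38, -0.09 for glycolysis with a mean of 0.13 and -0.18 for fibroblast genes (4 measured). Signs turned for WNT targets under 3 settings (-0.085 to -0.034), for fibroblast genes in plate rows A to D (0.36) and for glycolysis with the shift set to 0 (0.027). With medians over cells the formative pluripotency, WNT, fibroblast, epithelial-mesenchymal and X- and Y-linked lists had 0.

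The question stated for the cells themselves was whether they were heterogeneous. PrES cells were about as alike to one another as the cells of the other types, and the endoderm program was present in nearly all of them. Of the 12 primitive endoderm core genes, a PrES cell had a median of 11 at 10 CPM or more (range 6 to 12), and 89 of 92 cells had at least 8. The median was 9 in XEN (range 1 to 11, with 80 of 92 cells at 8 or more), 0 in ES and 1 in TS cells. Gata6 reached 10 CPM in 80.4% (70.9 to 87.97%) of PrES cells, Gata4 in 93.5% (86.3 to 97.6%), Sox17 in 94.6% (87.8 to 98.2%) and Pdgfra in 91.3% (83.6 to 96.2%). Pou5f1 reached it in 95.7% (89.2 to 98.8%), so epiblast and endoderm factors were found in the same cells: Sox17 and Pou5f1 were together at 10 CPM or more in 83 of 92 PrES cells (90.2%, 82.2 to 95.4%), against 1 ES, 5 XEN and 0 of 92 TS cells. For 0 of 92 cells, 3 counts of the total allow a share of up to 3.26%, and the Clopper-Pearson upper limit is 3.93%. Gata6 and Pou5f1 were together in 72 (78.3%, 68.4 to 86.2%), Gata4 and Nr0b1 in 79 (85.9%, 77.05 to 92.3%; 2 ES, 0 XEN and 16 TS cells), Gata6 and Nanog in 9 (9.78%, 4.57 to 17.8%), and Gata6 with Sox2 or with Cdx2 in none.

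**Figure D3:**
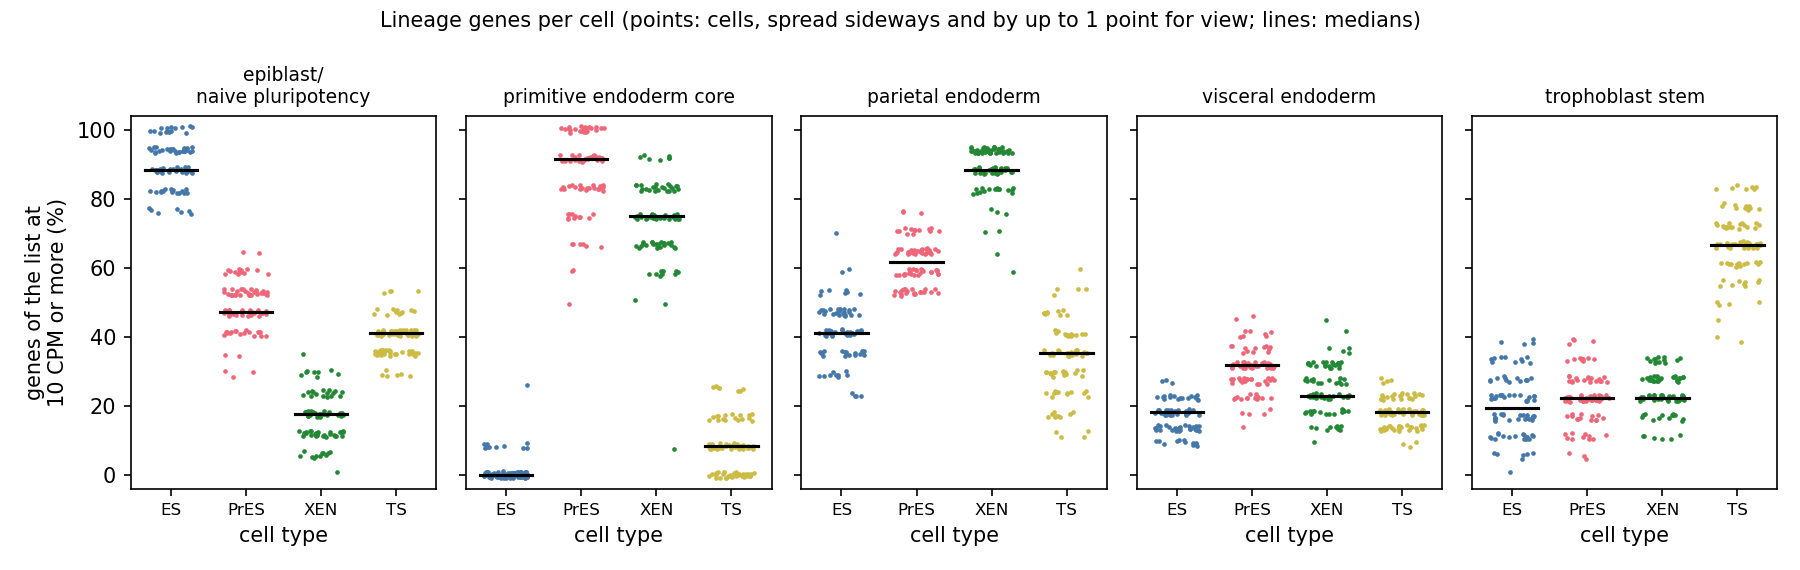
Share of the genes of 5 lineage lists that reached 10 CPM in each cell, for 92 cells of each type; points are cells, moved sideways and by up to 1 percentage point for view, and lines are medians. PrES cells have a median of 11 of the 12 primitive endoderm core genes, and 1 XEN cell has only 1 of them.

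A threshold of 10 CPM was needed for such shares because many genes of 1 type had counts at a low level in cells of another. How common these were depended on the types compared. For the 50 highest genes of a type that stayed under 5% of their level there, the median share of cells with a count varied. It ran from 17.4% (XEN genes in PrES cells) to 92.9% (XEN genes in ES cells). PrES genes had 84.8% in ES and 87% in TS cells, against 34.2% in XEN cells. Nanog had a count above 0 in 100% (96.1 to 100%) of XEN cells at a mean of 3.91 CPM, and Dab2 in 100% (96.1 to 100%) of ES cells at 5.92 CPM, although only 2 and 2 cells reached 10 CPM. Median depths were alike (2078968 counts in ES and 2190649 in XEN cells). For genes with high levels in another type, 10 CPM may not lie above this low level. Amn, at 1112 CPM in PrES cells, reached 10 CPM in 18 TS cells at a mean of 8.63 CPM there. Such genes may add to the counts of list members per cell. With any count above 0, Gata6 and Nanog were together in 87% (78.3 to 93.1%) of PrES cells, but also in 91.3% (83.6 to 96.2%) of XEN and 54.3% (43.6 to 64.8%) of ES cells, so the share in PrES cells was at the background and is not read as co-expression.

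The similarity of cells within a type was close in all types. The median pairwise correlation of log2(CPM + 1) over genes with a mean of at least 10 CPM was 0.514 in ES, 0.507 in PrES, 0.503 in XEN and 0.505 in TS cells. A division of each type into 2 groups of cells gave silhouettes of 0.188 in PrES, 0.127 in XEN and 0.177 in TS cells, against at most 0.0774, 0.0785 and 0.0789 after each gene was shuffled across cells. The shuffles remove all variation that genes share, so graded shared variation can also exceed them. The silhouettes therefore do not show that separate groups of cells exist. In ES cells the silhouette was 0.647 because the shallow cell of well D12 stood alone against the other 91, and without it the value was 0.104. The PrES division put 42 cells against 50, and the 42 had lower G2/M genes (median log2 ratio -1.80 over 18 genes, 53.8 against 183.8 CPM), which were among the genes the division could use. Leaving out the S phase and G2/M lists gave a silhouette of 0.176, which takes out the listed genes only and not the whole cell cycle. The G2/M difference between the 2 groups was -0.24 in XEN and -0.41 in TS cells. The silhouettes of XEN and TS cells depended on the genes and wells used: they were 0.303 and 0.358 with genes of at least 50 CPM, and 0.608 and 0.309 in plate rows A to D alone. Rows A to D hold the XEN cell of well B11 with fibroblast genes, which had the lowest median correlation with the other XEN cells (0.299). Whether this cell alone made the XEN value there was not tested.

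G2/M genes were the most variable of the fixed lists in PrES cells. Relative to the 200 genes nearest in mean, the squared coefficient of variation of G2/M genes had a median percentile of 96.3, with 14 of 18 genes in the top 10%, for example Top2a (220.2 ± 274.1 CPM) and Plk1 (183.4 ± 231.8). S phase genes had 89.8, primitive endoderm core genes 85.3, visceral endoderm genes 82.8 and parietal endoderm genes 78.5. Epiblast genes had 39, and Pou5f1 was at percentile 22. G2/M genes were at 93.3 in ES, 95.5 in XEN and 91.8 in TS cells. Among the other lists in PrES cells, stress and p53 genes had 94, glycolysis 89.5, epithelial-mesenchymal genes 88, DNA methylation 85.5, sterol synthesis 83.5, imprinted genes 81, trophoblast stem genes 76.5, X- and Y-linked genes 65.3, FGF and PDGF ligands and receptors 65.3 and FGF/ERK targets 44.3. Without the shallow cell of well A1, G2/M genes had 98, S phase genes 94, visceral endoderm genes 87 and parietal endoderm genes 85. Primitive endoderm core genes then had 85.3, epiblast genes 40, epithelial-mesenchymal genes 95 and sterol synthesis 89.

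The 10 most variable PrES genes with a mean of at least 50 CPM were Cdr2, Capn7, Arntl, Zranb2, Ube2g1, Pias2, Shc1, Uvrag, Mdm2 and Egln1. All 10 had their highest value in the shallow cell of well A1, which held between 58.4% and 95.8% of the summed CPM of each. Without that cell none of them remained among the first 10, which were Braf, Kpna2, Lefty1, Ahnak, Bnip3, Pabpc1, Gstm1, Cdc20, Lefty2 and Fkbp6. Lefty1 was then at 149.1 ± 330.7 CPM and reached 10 CPM in 49 of 91 cells, and Lefty2 at 426 ± 517 CPM in 77 of 91. In XEN cells the first 10 were Lox, Col1a1, Penk, Cxcl12, Col3a1, Wisp2, Bgn, Aqp8, Serpine2 and Clu. The first 7 had between 96.8% and 99.8% of their summed CPM in the cell of well B11: Col1a1, the main fibrillar collagen of fibroblasts, was at 6261 CPM there and at 0.231 ± 0.641 CPM in the other 91 XEN cells. Without this cell and the shallow one, the first 10 were Aqp8, Clu, S100g, H1f0, Igfbp2, Cyr61, Gpc3, Ctgf, Lamc2 and Grb10. Aqp8 was then at 210.7 ± 787 CPM, with 38.7% of its sum in 1 cell.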

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

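The 2 libraries of reads assigned to no well carried a signal above the limit that a count of 0 allows. They held 8403899 and 8699179 counts, 2.14% of all counts, over 20491 and 20603 genes. Their correlation with the mean profiles, across all 36040 genes, was 0.956, 0.962, 0.959 and 0.961 for ES, PrES, XEN and TS cells in the first library. In the second it was 0.956, 0.962, 0.958 and 0.961. Without a filter on low values the types themselves correlated at 0.910 to 0.95 with one another. Markers of all 4 types were present: Nanog at 265.2 and 258.2 CPM, Dab2 at 673 and 659, Hand1 at 266.1 and 256.9, and Amn at 283.6 and 280.03. No explanation was tested.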

How the results depend on the processing

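Leaving out cells under 500000 counts, leaving out the XEN cell with fibroblast genes and CPM without LOC101056014 were chosen after the data were seen. No paired analysis was possible because each type is 1 sample. Of 42 main values, 13 stayed within the set limits under all settings run for them. Among the values of these 42 under the alternatives, 397 stayed within the limits, 57 moved and 3 of at least 2-fold changed sign; among all others the numbers were 3679, 658 and 14. Ratios under 2-fold changed sign 8 more times among the first and 37 times among the others, and 3 and 52 ratios went to 0. For gene ratios of at least 2-fold, 3055 of 3094 values kept their sign. This total includes settings that cannot turn the sign of a gene ratio, so it overstates stability. They are the other pseudocounts, which were added alike to both means, and the cell filters that removed no cell. All 39 values with another sign or 0 came from the remaining settings. The cell filters of 0 and 4000 genes removed no cell, so they say nothing about stability. Marker levels were not run under centring or without the low filter, which cannot apply to them. The cause of a change was not tested unless named. Depth limits low levels most in the 3 cells under 500000 counts.

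Against XEN cells, the trophoblast stem list had -0.25 under a pseudocount of 10, -2.67e-04 with means of logs, 0.33 with medians over cells, 0.014 in plate rows E to H and 0.055 without the low filter. The epiblast list moved to 1.84 with a pseudocount of 10 and 1.495 without the low filter. The imprinted list changed sign with means of logs (0.16) and medians (0.082), as did Tdgf1 (-0.56 and -0.99). Gata3 changed to 0.55 with medians, and in rows E to H Rbp4 changed to 0.29 and Gata2 to 0.014. Without the XEN cell with fibroblast genes the fibroblast list was at -0.13 and the imprinted list at -0.27, and without the shallow cells Gata4 was at -1.03.

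Against ES cells, pseudocounts of 0.1 and 10 gave 7.44 and 4.31 for the primitive endoderm core list and 3.53 and 2.16 for the parietal list. Medians over cells gave 2.29 for the parietal, 0 for the visceral and 0.56 for the trophoblast stem list (0.31 with means of logs, 0.28 in rows E to H). The imprinted list changed sign with means of logs (0.12) and medians (0.67), as did Gata3 (0.58 and 1.71). Without the shallow cells Tfap2c was at -4.42.

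Against TS cells, pseudocounts of 0.1 and 10 gave 4.23 and 0.82 for the visceral and -4.01 and -1.69 for the trophoblast stem list, and a pseudocount of 10 gave 4.06 for the primitive endoderm core and 1.61 for the parietal list. Medians over cells gave 1.76 for the parietal and 0 for the visceral list, means of logs 0.73 and no low filter 1.11 for the visceral list, and rows E to H -3.57 for the trophoblast stem list. The epiblast list changed sign with means of logs (0.302), medians (0.296), rows A to D (0.131), centring (0.087) and no low filter (0.13). Plat changed sign with means of logs (-0.46), medians (-0.56) and rows A to D (-0.23).

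With means of logs, the median level of the primitive endoderm core list was 6.84 in PrES and 5.98 in XEN cells, and that of the trophoblast stem list in TS cells 6.45 (7.08 with medians). With genes of at least 10 CPM the profile correlations were 0.728 (ES and PrES), 0.672 (ES and XEN), 0.709 (ES and TS), 0.828 (PrES and XEN), 0.731 (PrES and TS) and 0.689 (XEN and TS). Without the low filter they were 0.925, 0.910, 0.924, 0.95, 0.928 and 0.918 in the same order, and ES and TS had 0.773 with a pseudocount of 0.1.

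With genes of at least 50 CPM the median correlation between cells was 0.428 in ES, 0.416 in PrES, 0.414 in XEN and 0.412 in TS cells, and the silhouettes were 0.253 in ES, 0.303 in XEN and 0.358 in TS cells. The ES silhouette was also 0.0956 after thinning, 0.596 in rows A to D, 0.122 in rows E to H and 0.104 without the shallow cell, which by itself made 1 of the 2 groups. The XEN silhouette was 0.608 in rows A to D, and the TS one 0.309 there and 0.124 with a pseudocount of 0.1. In PrES cells the percentile of the parietal list was 68.5 with the variance of logs and that of the visceral list 72 in rows A to D. Gata6 and Nanog were together in 62% of PrES cells at 1 CPM and in 9.78% at 10 CPM, against 87% above 0. None of the 10 most variable PrES genes was shared under the variance of logs, in rows E to H or without the shallow cell, and all 10 were under the other settings.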

Other observations

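Sex-linked genes differed between the types. The summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty reached 10 CPM in 85 of 92 PrES cells (92.4%, 84.95 to 96.9%) and 88 XEN cells (95.7%, 89.2 to 98.8%), against 52 ES cells (56.5%, 45.8 to 66.8%) and 5 TS cells (5.43%, 1.79 to 12.2%). Xist, the RNA that coats the inactive X chromosome, reached it in 49 TS cells (53.3%, 42.6 to 63.7%), 13 ES, 8 PrES and 1 XEN cells. Both were at 10 CPM or more in 9 ES, 8 PrES, 1 XEN and 2 TS cells. The labels do not give the sex of the line a cell came from.

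Imprinted genes were among the most variable genes of XEN and TS cells. In XEN cells all 8 measured members lay in the top 10% of variation (median percentile 98), and in TS cells 7 of 10 did (97.5). Without the XEN cell with fibroblast genes Mest fell below the minimum mean of 10 CPM, and the 7 that remained were all in the top 10% (98.5). Cdkn1c, an inhibitor of the cell cycle, was at 335.4 ± 616 CPM in TS cells and H19, a growth-restraining RNA, at 609 ± 684. In PrES cells 2 of 5 were in the top 10% (81).

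In the patterns that follow, the gene choice and decision rule of the test on plate positions and the sum without Dab2 were chosen after values were seen; of 3 earlier rules for the positions, which set limits on the low level, 2 gave no verdict. Genes of 1 type were found at a low level in cells of another, at a median of 0.610% to 1.32% of the source level for the 50 highest source genes that stayed under 5% of it. In 8 of 12 ordered pairs of types the counts followed the source plate's rows or columns above all 100 shuffles. Chance gives 0.238 for independent pairs. These are not independent, since each 2 types were compared in both directions. The test used counts that were not divided by the totals of the cells. Depth that varied alike over the rows or columns of 2 plates could therefore give the same result, and this was not tested. So the position test by itself does not decide whether low transcription in the receiving cells was the whole cause. By row the pairs were ES with PrES (r = 0.0986 and 0.116) and XEN with TS (0.123 and 0.111). By column they were ES with XEN (0.229 and 0.166) and PrES with TS (0.177 and 0.201). XEN genes in TS cells also lay above all shuffles by column (0.0473, highest shuffle 0.0410). With genes specific to the source they did not (0.0214, highest shuffle 0.0370). There was none for ES with TS or PrES with XEN. The same 8 pairs came out with genes specific to the source, in the same wells and counts. For PrES genes this rests on few counts (source median 3.19 CPM, counts in a median of 1.09% of ES cells). ES genes had counts in a median of 21.7% of PrES, 34.8% of XEN and 5.43% of TS cells. XEN genes had 20.7% in ES, 2.17% in PrES and 14.1% in TS cells. TS genes had 9.24% in ES, 56.5% in PrES and 35.3% in XEN cells. The lowest share was each time in the type without a position signal, though median depths were close. These shares argue against low transcription as the whole cause for the ES, XEN and TS genes. Reads assigned across wells of plates that share an index would give the position signal and such shares, and may account for part of the low level. No biological explanation beyond low transcription was tested.

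The 10 most variable PrES genes may reflect 1 shallow library with few molecules. The PrES cell with the lowest total, 117511 counts, held a median of 69.7% of their summed CPM, where over 50% was predicted. That share by itself leaves no room for a group of at least 5 PrES cells sharing high levels, and the median number of cells with at least 25% of the highest level, 1, restates it and is not a second test. What sets the variation of the genes that lead without that cell, such as Lefty1 and Lefty2, was not tested.

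The XEN cell of well B11 had a summed fibroblast level of 17921 CPM, against at most 287 in the other XEN cells and 112.8 in the other types, with Col1a1 at 6261, Col3a1 at 5131 and Col1a2 at 3385 CPM. The growth protocol mentions mouse embryonic fibroblast feeders. Its primitive endoderm core sum was 8.86% of the median of the other XEN cells, above the limit of 5% set beforehand for a fibroblast alone and below the 25% set for a fibroblast together with a XEN cell, but 322.3 of the 332.4 CPM came from Dab2, and without Dab2 the sum was 0.371%. On that later measure a fibroblast together with a XEN cell in 1 well is argued against, and a fibroblast alone in the well is a candidate explanation. For 2 cells in 1 well, counts and genes in the upper part of the XEN cells had also been predicted. The cell's 2367741 counts were above the XEN median of 2190649, while its 7973 genes were below the median of the other XEN cells (8730.0). Read totals without molecular identifiers need not follow the number of cells, so the total by itself says little. A XEN cell that had changed its type was not tested.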
